A study of Mus musculus with 6 samples.

How the data were processed

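The labels place 6 arrays of mouse cerebral cortex RNA in 2 groups, wild type and Egr1 and Egr3 double knockout, with 3 arrays each, and number the replicates of each group. They give no protocol, strain, sex, age, batch or pairing. The groups were taken from the descriptions. The title of double knockout replicate 1 has the wording of the wild type titles, which names an RNA extraction and no genotype, while those of double knockout replicates 2 and 3 name the double knockout. The deposited values are linear probe set intensity signals, already summarised and scaled by the authors. The software, its settings and the genome build were not given in the sources used here. After trimming 2% at each end, the mean of each array lay at 150.0, so brightness had been set equal between arrays and differences in total RNA cannot be seen. All columns of the table were used, and 0 pairs of arrays held identical values.

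The table held 45037 probe sets besides 64 control probe sets. The platform's annotation gave 1 gene symbol for 34945 of them, several for 932 and none for 9160, and only probe sets with 1 symbol were named. Symbols were updated by gene number in a RefSeq gene table of assembly GRCm38.p6. That table was used only for names and for which genes neighbour each other, since the array values name no build.

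Signals under 1 were set to 1 (4.35% of values) and log2(signal + 16) was taken. Array medians on this scale differed by 0.0885, so the deposited scaling was kept. Probe sets were tested if their mean log2 signal over all 6 arrays lay above the median of all probe sets. These were 22518, of which 19574 had 1 symbol for 11053 genes, 503 several and 2441 none. Group differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit with group as the only term, eBayes with an intensity trend). Two-sided p-values were adjusted by the Benjamini-Hochberg method, with an adjusted p under 0.05 as the threshold. Log2 differences are double knockout label minus wild type. Gene lists for cortex, Egr targets and other cell types and regions were tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry. Each gene was represented by its brightest tested probe set, and 24 lists had the minimum of 5 measured genes. Neighbourhood of Egr1 and Egr3 was tested with the two-sided Fisher's exact test in windows of 5, 10 and 20 Mb, without Egr1 and Egr3 themselves, for the 11019 of 11053 genes with a position. An exact permutation test of 3 arrays against 3 cannot go below a two-sided p of 0.1 and was not used. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

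The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names the Egr family with Nab1 and Nab2, Arc, and the 12 largest rises and 12 largest falls past the threshold with 1 symbol and no overlap between groups. It adds up to 4 passing members of each list by size of change, or else the 2 with the smallest p as values, and the sex-linked genes and controls. Alternatives were pseudocounts of 1 and 64, quantile normalization, a shift to the common median, no filter and a stricter filter at the 75% quantile. Others were no intensity trend, a robust trend, array weights, each replicate left out, other thresholds, the replicate number as a block and, for lists, the mean of a gene's probe sets. The groups share only replicate numbers, so the main comparison is unpaired.

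The limma step was tested on simulated data, with 22518 probe sets tested and 200 changed in each of 10 draws from the real means and spreads. It recovered 17.8% of probe sets changed by 0.5 on the log2 scale, 82.6% of those changed by 1, 86.2% by 1.5 and 86% by 2. A changed probe set that dropped below the filter counted as missed, and simulated signals were floored at 1. These shares therefore reflect the filter and the floor as well as limma. Of the calls of the limma step 7.97% were false, above the nominal 5%. With no change simulated it made 0 calls and called 0 lists, and with the cholesterol list lowered it called 1 list. The simulated probe sets were drawn independently, so this does not check the list test for members that vary together. In the real data the estimated correlation of the 5 lists called with the preset was 0.267 to 0.618.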

Results

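Gene expression in the cerebral cortex of mice was measured on 6 Affymetrix mouse expression arrays. Total RNA of 3 arrays was labelled wild type and that of the other 3 Egr1 and Egr3 double knockout. Egr1 and Egr3 encode zinc finger transcription factors of the early growth response family, which neurons induce rapidly with activity. The comparison asks which cortical transcripts differ when both factors are targeted, with Arc, an activity-induced gene of the postsynaptic cytoskeleton, among the genes of interest. Array medians lay between 36.2 and 39.6 signal units, and the number of arrays limits the precision. The labels do not say that the arrays of a group came from separate animals, so the p-values measure only the spread between these arrays.

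Across probe sets, log2 signals correlated with Pearson's r from 0.980 to 0.981 among wild type arrays and from 0.979 to 0.983 among arrays labelled double knockout. Between the groups r lay from 0.973 to 0.980; probe sets are not independent replicates. Double knockout replicate 2 carried RNA of a female, with an Xist signal of 3140 and an Eif2s3y signal of 0.630. The other 5 arrays read at most 42.5 for Xist and at least 383 for Eif2s3y. In wild type replicate 1 the spiked controls bioB, bioC, bioD and creX read 0.408 to 0.433 of the median of the other arrays. The ratio of the 3' to the 5' Gapdh control probe set, a sign of RNA quality, did not overlap between the groups. It was 0.842, 0.806 and 0.873 in wild type and 0.922, 0.9497 and 0.881 in the arrays labelled double knockout. The same ratio for Actb overlapped, at 1.58, 1.67 and 1.95 against 1.89, 1.68 and 1.75. Choroid plexus genes were high in wild type replicate 3 alone, where the median of the 5 measured genes stood 1.49 above their wild type mean on the log2 scale. It stood at -0.60 and -0.85 in the other wild type arrays and at -0.67 to -0.22 in the arrays labelled double knockout.

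Egr3 signal fell in the arrays labelled double knockout, whereas Egr1 signal did not. The brighter Egr3 probe set read 1594 ± 941 (SD, n = 3) in wild type and 405 ± 89.8 (SD, n = 3) in the arrays labelled double knockout. This was a log2 change of -1.80 (SE 0.32, limma adjusted p = 0.0361), with all 3 arrays below all 3 wild type arrays. A dim Egr3 probe set, below the filter and not tested, read 40.3 ± 3.91 and 17.6 ± 3.35. The Egr1 probe set read 1577 ± 423 (SD, n = 3) in wild type and 2473 ± 309 (SD, n = 3) in the arrays labelled double knockout. The log2 difference was 0.67 (SE 0.17, limma adjusted p = 0.108), with all 3 arrays above all 3 wild type arrays. Both Egr3 probe sets went with the label. The Egr1 signal did not, though its difference was not past the threshold. Its nearest arrays, double knockout replicate 1 and wild type replicate 2, read 2116 and 2054. The group is therefore called by its label throughout. The positions of the probes and the deleted parts of the genes were not given in the sources used here. A probe set outside a deleted part checks nothing about the label.

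No other member of the family or its corepressors passed the test. The log2 difference was 0.74 for Egr2 (SE 0.41, limma adjusted p = 0.402) and 0.21 for Egr4 (SE 0.25, adjusted p = 0.722). Nab1 and Nab2, corepressors that bind Egr proteins, differed by 0.31 (SE 0.10, adjusted p = 0.162) and 0.50 (SE 0.19, adjusted p = 0.230). A second tested Nab1 probe set differed by 0.16 (SE 0.13, limma adjusted p = 0.593). Of the 6 genes 1 fell and 5 did not pass. Egr1, Nab1 and Nab2 rose and Egr3 fell adjusted over the list alone, and the list's median log2 difference was 0.41 (camera adjusted p = 0.263). Arc read 94.6 ± 54.4 in wild type and 108 ± 75.1 in the arrays labelled double knockout, a log2 difference of 0.15 (SE 0.47, limma adjusted p = 0.913). The Arc difference turned to -0.36 without wild type replicate 1 and to -0.31 without double knockout replicate 3. The Egr3 call was lost without wild type replicate 1 (adjusted p = 0.0784), without double knockout replicate 1 (0.0932), without double knockout replicate 2 (0.159) and without double knockout replicate 3 (0.0845), and with no filter, no intensity trend or robust trend, in a range of 0.00846 to 0.249. The Egr1 difference passed only without wild type replicate 2 (log2 0.87, adjusted p = 0.0172), in a range of 0.0172 to 0.442, and the list passed only without double knockout replicate 1 (median 0.60, adjusted p = 0.0432), in a range of 0.0432 to 0.799.

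**Figure D1:**
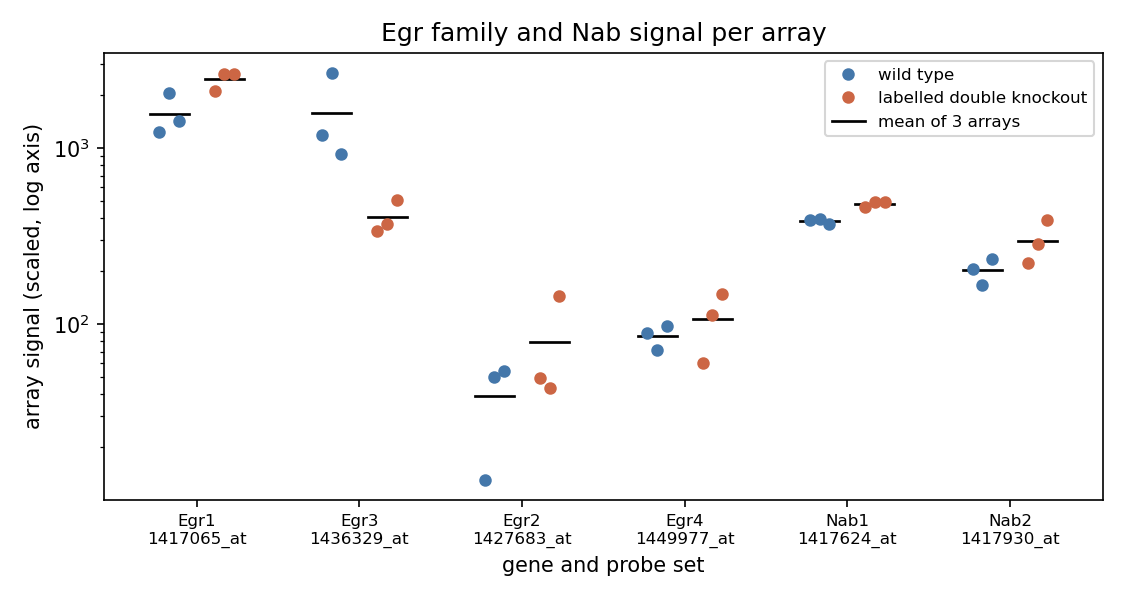
Array signal (log axis) of 1 probe set for each of Egr1, Egr3, Egr2, Egr4, Nab1 and Nab2; points are single arrays, blue for wild type and orange for arrays labelled double knockout, and black lines are means of 3 arrays. The arrays labelled double knockout sit below all wild type arrays for Egr3 (means 405 and 1594) and above them for Egr1 (means 2473 and 1577).

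Pttg1, which encodes securin, an inhibitor of sister chromatid separation, showed the largest change. Its signal was 1327 ± 342 (SD, n = 3) in wild type and 85.0 ± 16.01 (SD, n = 3) in the arrays labelled double knockout, a log2 change of -3.72 (SE 0.18, limma adjusted p = 3.18e-05). Tnnc1, encoding a troponin C, fell from 382 ± 40.7 to 37.4 ± 10.02 (log2 -2.91), and Myh7, encoding a myosin heavy chain, from 245 ± 87.0 to 19.3 ± 5.13 (log2 -2.85). Their signals in the arrays labelled double knockout were near or below the array medians, so the size of the fall depends on the pseudocount, with log2 values of -3.34 to -2.14 and -3.58 to -1.86 over the alternatives. The same limit applies to Arhgap6 (1.60 to 2.86), Cpne9 (-2.90 to -1.61), Pcdhb9 (-2.40 to -1.29) and Frzb (-1.92 to -1.05). Other dim probe sets named here also moved over the alternatives, among them Scn4b (-1.59 to -0.78), Rbfa (-1.98 to -1.17), Gpr83 (-1.72 to -1.09), Kcnab3 (0.80 to 1.45) and Nrtn (0.76 to 1.42). The largest rise was that of Arhgap6, from 33.4 ± 15.9 to 233 ± 64.2 (log2 2.36, SE 0.27, limma adjusted p = 0.00762). Etnppl, an enzyme that breaks down phosphoethanolamine, rose from 58.2 ± 25.7 to 289 ± 109 (log2 2.02, SE 0.30, adjusted p = 0.0166).

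Of 22518 probe sets tested, 229 passed an adjusted p of 0.05 in limma, 96 higher and 133 lower in the arrays labelled double knockout. They named 172 genes, 70 that rose and 102 that fell. The median fold was 1.84 on the log2(signal + 16) scale, which understates the change of dim probe sets, and 74 probe sets changed by at least 2-fold. The values of the groups did not overlap for any of the 229, nor for 5011 (22.3%) of all tested probe sets, where chance gives 10%.

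Among the 12 largest falls, Cpne9, a copine that binds membranes in response to calcium, went from 221 ± 40.0 to 29.2 ± 7.66 (log2 -2.39). Hpcal1, a neuronal calcium sensor, fell from 1198 ± 561 to 282 ± 110 (log2 -1.97). Syt4, a synaptotagmin, fell from 791 ± 173 to 255 ± 25.8 (log2 -1.56), though a second probe set differed by -0.20 and did not pass. Pcdhb9, a clustered protocadherin, changed by -1.97, Rbfa, a ribosome binding factor, by -1.69, Frzb, a secreted Wnt antagonist, by -1.59, and Gpr83, a G protein-coupled receptor, by -1.51. Khdrbs1, an RNA-binding protein, changed by -2.11 on 1 of its 5 tested probe sets, while the brightest of the others differed by -0.17. Pcdhb9 and Syt4 lie within 10 Mb of Egr1, and Myh7 within 20 Mb of Egr3. Further changed genes lie on the same chromosomes outside these windows. On the chromosomes of Egr1 and Egr3 22 genes changed, against 14 within 20 Mb of either gene. The other falls named above are not placed by chromosome here.

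Among the 12 largest rises, Col6a1, a collagen VI chain, went from 260 ± 54.6 to 705 ± 112 (log2 1.39). Nrtn, which encodes the trophic factor neurturin, rose from 47.5 ± 16.9 to 124 ± 12.02 (log2 1.17), and S1pr3, a receptor for a sphingolipid, from 134 ± 4.88 to 323 ± 27.3 (log2 1.17). Cap1, an actin regulator, rose by 1.98 on 1 probe set while the other differed by 2.12 and did not pass, Sbsn, which encodes suprabasin, by 1.65, and Zfas1, a noncoding host of small nucleolar RNAs, by 1.37. Kcnab3, a potassium channel subunit, rose by 1.21 and Bcl2l11, a promoter of apoptosis, by 1.13. The transcription factors Tshz2 and Pou3f1 rose by 1.20 and 1.15, and a second Tshz2 probe set differed by 0.17 and did not pass. The count of 229 fell to 97 without wild type replicate 1, 143 without double knockout replicate 1, 53 without double knockout replicate 2 and 34 without double knockout replicate 3. The excess of falls turned without wild type replicate 3 (95 higher and 83 lower), and among these fits the share of rises was lowest without double knockout replicate 2 (16 higher and 37 lower). The count of 229 became 12 without both the array with dim controls and the array of the female, 10 with no filter and 131 with no intensity trend. Of the 40 named probe sets past the threshold, 20, 36 and 31 kept it without wild type replicates 1, 2 and 3, and 29, 17 and 13 without double knockout replicates 1, 2 and 3.

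**Figure D2:**
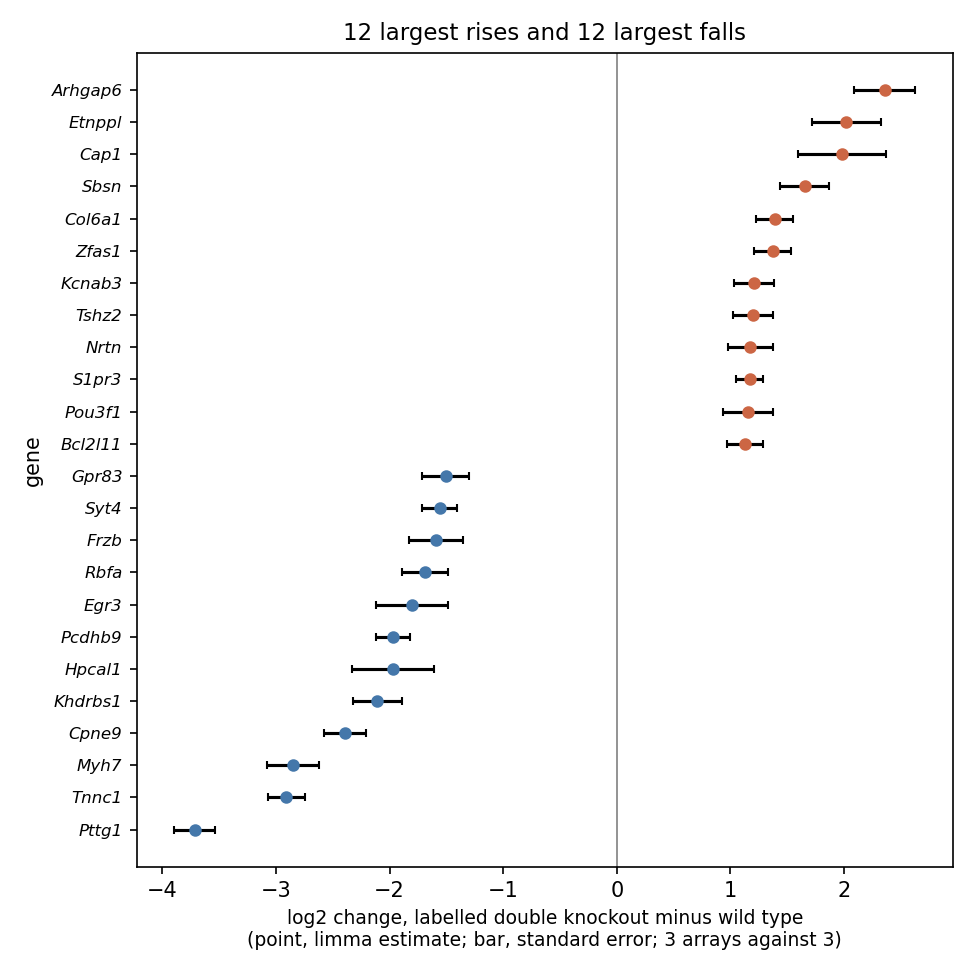
Log2 change (horizontal axis) of the 12 genes with the largest rise and the 12 with the largest fall in the arrays labelled double knockout against wild type, 3 arrays in each; points are limma estimates and bars are standard errors. Values run from -3.72 for Pttg1 to 2.36 for Arhgap6.

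Cholesterol synthesis genes were lower in the arrays labelled double knockout, in 13 of 15 measured genes. The enzymes Msmo1 (971 ± 121 to 481 ± 62.2, log2 -0.99), Cyp51 (420 ± 58.8 to 213 ± 14.9, log2 -0.92), Idi1 (506 ± 65.2 to 280 ± 42.5, log2 -0.82) and Nsdhl (371 ± 56.9 to 221 ± 11.3, log2 -0.70) fell. None rose, 11 did not pass, and adjusted over the list alone 9 fell. Hmgcs1 and Fdft1 fell on a dimmer probe set (log2 -0.73 in each), and Fdft1 lies within 10 Mb of Egr3. The list's median log2 difference was -0.45 (camera adjusted p = 7.51e-07 with a preset correlation, adjusted p = 0.799 with an estimated correlation). The per-array medians were -0.46, -0.36 and -0.60 in the arrays labelled double knockout and 0.18, -0.23 and 0.01 in wild type.

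Microglia genes were lower in all 14 measured members, with a median log2 difference of -0.46 (camera adjusted p = 1.97e-06, adjusted p = 0.799 with an estimated correlation). None passed over all probe sets, and 6 fell adjusted over the list alone. P2ry12, a purinergic receptor of microglia, read 326 ± 56.6 and 194 ± 52.6, and Laptm5, a lysosomal membrane protein, 208 ± 17.6 and 137 ± 21.1. The per-array median was -0.11 in double knockout replicate 1, next to -0.10 in wild type replicate 2, and -0.52 and -0.51 in the other arrays labelled double knockout. Without both wild type replicate 1 and double knockout replicate 2 the list's median was -0.28. P2ry12 passed without double knockout replicate 1 (log2 -0.91, adjusted p = 0.0472, in a range of 0.0472 to 0.445).

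Heat shock and chaperone genes had a median log2 difference of -0.26, with 15 of 19 lower (camera adjusted p = 0.00129, adjusted p = 0.799 with an estimated correlation). None passed on the brightest probe set, and Hsph1, Hsp90b1 and Calr fell adjusted over the list alone. Hsph1 read 2128 ± 170 and 1496 ± 156, and Hsp90b1 1382 ± 210 and 966 ± 107. Hsph1 and Hspa1b fell on a dimmer probe set (log2 -0.71 and -0.96). The per-array medians overlapped, at -0.04, -0.45 and -0.23 in double knockout replicates 1, 2 and 3 and -0.19, 0.23 and -0.02 in wild type. The list's median moved to -0.14 without wild type replicate 2, -0.40 without double knockout replicate 1, -0.15 without double knockout replicate 2 and -0.11 with the stricter filter.

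Of 14 neurotrophin and growth factor genes 10 were lower, with a median of -0.18 (camera adjusted p = 0.0307, adjusted p = 0.799 with an estimated correlation). Ntrk3, the receptor of a neurotrophin, fell from 417 ± 16.4 to 275 ± 8.85 (log2 -0.57, limma adjusted p = 0.0337) and 13 did not pass. Bdnf fell too adjusted over the list alone, and read 265 ± 80.4 and 123 ± 26.9 (limma adjusted p = 0.0549). The per-array medians were -0.23, -0.16 and -0.20 in the arrays labelled double knockout and -0.09, 0.20 and -0.11 in wild type. The list's call was lost without wild type replicate 2 (median -0.11, adjusted p = 0.188), without double knockout replicate 1 (adjusted p = 0.178), with array weights (adjusted p = 0.0636) and with the mean of a gene's probe sets (adjusted p = 0.246), in a range of 0.00502 to 0.799.

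Genes that respond to glucocorticoids were higher in 13 of 15, with a median log2 difference of 0.28 (camera adjusted p = 0.0167, adjusted p = 0.799 with an estimated correlation). None passed over all probe sets, and Sgk1 (671 ± 50.4 and 1075 ± 246) and Sult1a1 (109 ± 49.9 and 275 ± 111) rose adjusted over the list alone. The per-array medians overlapped, at 0.03, 0.55 and 0.34 in double knockout replicates 1, 2 and 3 and -0.01, -0.02 and 0.04 in wild type. The highest was that of the array of the female. The call was lost without double knockout replicate 2 (adjusted p = 0.251) and without both doubted arrays (0.294), in a range of 8.79e-07 to 0.799, and the median was 0.46 without double knockout replicate 1. Of 24 lists tested these 5 passed with the preset correlation. With an estimated correlation or with the directional test of fry 0 passed, its adjusted p for the 5 lying between 0.340 and 0.678. The mixed test of fry, which asks for change in either direction and makes no comparison with other genes, passed for 16 of the 24. Of the 5 it passed for the cholesterol (adjusted p = 0.00622), microglia (0.0451) and neurotrophin lists (0.00300) and not for the heat shock (0.0812) and glucocorticoid lists (0.165). Over all tested probe sets 3735 had an unadjusted limma p under 0.05.

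**Figure D3:**
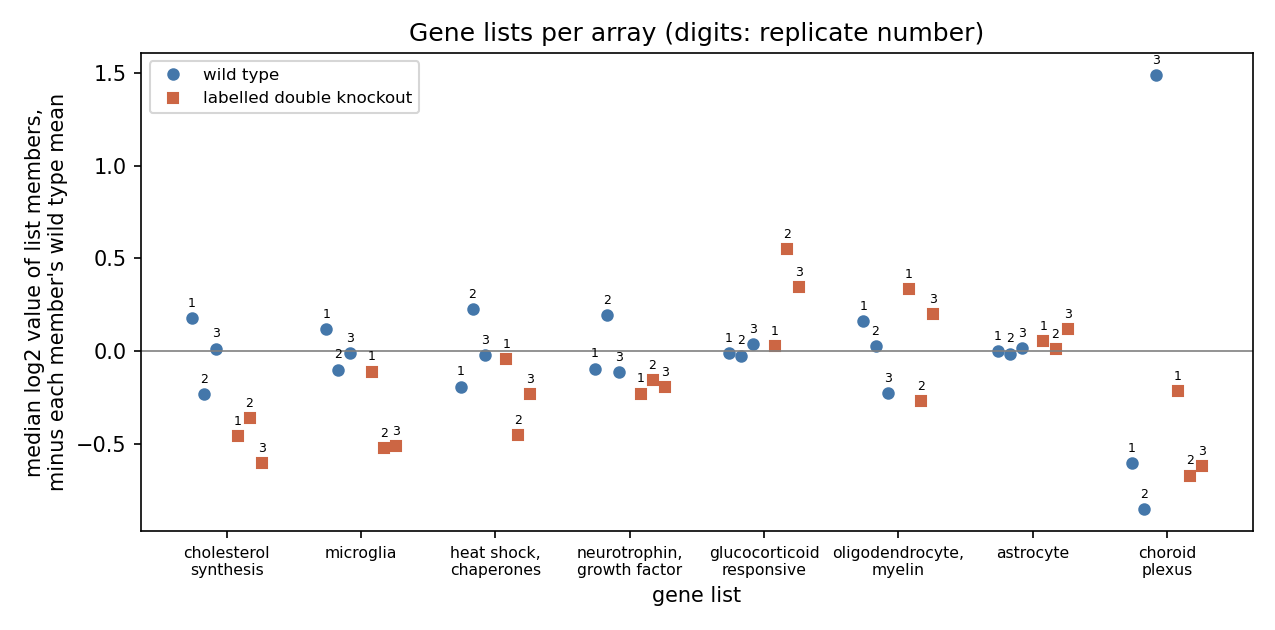
Median log2 value of the members of 8 gene lists in each array, after subtracting each member's wild type mean (vertical axis); circles are wild type arrays, squares are arrays labelled double knockout, and digits are replicate numbers. Cholesterol synthesis genes lie at -0.60 to -0.36 in the arrays labelled double knockout, below all wild type arrays, and choroid plexus genes stand at 1.49 in wild type replicate 3.

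Camera called none of the lists of Egr targets, immediate early, interneuron, GABA, ion channel, glutamate or presynaptic genes with all 6 arrays, and each held 0 to 2 changed genes. The mixed test of fry passed for each of them (adjusted p = 0.00276 to 0.0199) but the glutamate list (0.122). Members named only for passing within their list were chosen after their values were seen. Ache, acetylcholinesterase, rose among 14 reported Egr targets (169 ± 38.5 to 351 ± 47.9, log2 0.998, limma adjusted p = 0.0307) and 13 did not pass. Adjusted over the list alone Ache, Sgk1 and Nab1 rose and Bdnf and Maob fell (median 0.06, camera adjusted p = 0.680); 9 of the 14 are held by other lists. None of 31 immediate early genes passed, 5 of which other lists hold. Adjusted over the list alone Plk2, Dusp1 and Ier2 rose and 7 fell (median -0.0037, camera adjusted p = 0.485). Jund stood at 980 ± 113 and 643 ± 63.9 (log2 -0.59, limma adjusted p = 0.0504), and passed in 6 alternatives, among them without wild type replicate 2 (-0.69, adjusted p = 0.0234, in a range of 0.0234 to 0.330).

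Calb1, which encodes the calcium buffer calbindin, fell from 2292 ± 322 to 1129 ± 89.7 (log2 -1.005, limma adjusted p = 0.00913). The neuropeptide gene Vip rose from 1163 ± 87.5 to 1713 ± 145 (log2 0.55, adjusted p = 0.0453), and 17 of the 19 interneuron and neuropeptide genes did not pass. Vip and Cort rose and Calb1 and Tac1 fell adjusted over the list alone (median -0.12, camera adjusted p = 0.485). The list passed without wild type replicate 2 (median -0.16, adjusted p = 0.0458), in a range of 0.0458 to 0.799. Gabra2, a GABA-A receptor subunit, fell from 673 ± 93.6 to 431 ± 24.7 (log2 -0.62) and 15 of 16 GABA genes did not pass. Gabrd joined it adjusted over the list alone (median -0.05, camera adjusted p = 0.581). The potassium channel subunit Kcnv1 (log2 -0.97) and the sodium channel subunit Scn4b (log2 -1.27) fell among 29 voltage-gated channel genes, and 27 did not pass. Kcnd3 also fell and Kcnq3 rose adjusted over the list alone (median -0.02, camera adjusted p = 0.596). Vip, Gabra2 and Scn4b each lost the call in 5 of the 6 fits with 1 array left out.

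No member passed among 25 glutamate receptor and postsynaptic genes or 20 presynaptic genes, over all probe sets or adjusted over the list alone. Their medians were -0.01 (camera adjusted p = 0.596) and 0.07 (camera adjusted p = 0.485). Homer2 differed by -0.44 and Grm2 by 0.48 in the first list, and Unc13a by -0.40 and Sv2a by 0.31 in the second.

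Markers of other cell types and regions held few changed genes, and camera called none of these lists with all 6 arrays but that of microglia. The mixed test of fry passed for the hippocampal (adjusted p = 0.00300), astrocyte (0.00585), excitatory neuron (0.0158), endothelial (0.0304) and meningeal lists (0.0465), as it did for the Egr family (0.00455) and the reference genes (0.00276). The 15 oligodendrocyte genes had a median log2 difference of 0.12 (camera adjusted p = 0.601), with none past the threshold or adjusted over the list alone, Olig2 at -0.48 and Cnp at 0.28. The list passed without double knockout replicate 2 (median 0.25, adjusted p = 0.0376) and without both doubted arrays (median 0.32, adjusted p = 0.00230), in a range of 0.00230 to 0.960. Aqp4, the water channel of astrocyte endfeet, fell from 967 ± 7.67 to 495 ± 100 (log2 -0.96, limma adjusted p = 0.0139) among 15 astrocyte genes, and lies within 20 Mb of Egr1. Adjusted over the list alone Gjb6, Slc1a3 and Glul rose and Aqp4 and S100b fell. The astrocyte median (-0.0084) and mean (-0.05) were below 0 while camera ranked the list up (adjusted p = 0.964). Lmo4, a transcriptional cofactor, rose (log2 0.60, limma adjusted p = 0.0442) among 18 excitatory neuron and layer genes (median 0.12, camera adjusted p = 0.195). Lmo4 lost its call in each of the 6 fits with 1 array left out (adjusted p = 0.0682 to 0.187), and the list passed without wild type replicate 2 (median 0.22, adjusted p = 0.00606, in a range of 0.00606 to 0.799). Fezf2 and Crym also rose and Neurod6 fell adjusted over the list alone. None of 14 endothelial and mural genes passed (median -0.07, camera adjusted p = 0.596), Rgs5 (log2 -0.63) fell adjusted over the list alone, and Itm2a stood at -0.38.

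The transcription factor gene Zbtb20 fell (log2 -0.52, limma adjusted p = 0.0475) among 7 hippocampal genes (median -0.16, camera adjusted p = 0.593), and Neurod1 rose adjusted over the list alone. Zbtb20 lost its call in each of the 6 fits with 1 array left out (adjusted p of at least 0.0569). Igfbp2, an insulin-like growth factor binding protein, fell from 541 ± 132 to 243 ± 27.7 (log2 -1.08, limma adjusted p = 0.0225) among 13 meningeal fibroblast genes (median -0.06, camera adjusted p = 0.313). Dcn fell too and Ptgds rose adjusted over the list alone. None passed, over all probe sets or adjusted over the list alone, among 12 striatal genes (median -0.05, camera adjusted p = 0.581) or 10 thalamic genes (median 0.04, camera adjusted p = 0.596). Tac1 stood at -0.46 and Penk at -1.10 in the former, Rgs16 at 0.31 and Rora at 0.27 in the latter, and Penk passed without wild type replicate 2 (log2 -1.68, adjusted p = 0.00372, in a range of 0.00372 to 0.635). The same held for 5 choroid plexus genes (median -0.70, camera adjusted p = 0.263), with Clic6 at -0.61 and Kcnj13 at -0.70, and the median was 0.18 without wild type replicate 3. The list passed without wild type replicate 2 (median -1.06, adjusted p = 0.0410) and with no filter (median -0.58, adjusted p = 0.0325), in a range of 0.0325 to 0.911. No member passed among 10 interferon and MHC class I genes either, with Ifi27 at -0.39 and Stat2 at 0.27. Their median (0.02) and mean (0.0067) were above 0 while camera ranked them down (adjusted p = 0.955).

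The ribosomal protein gene Rplp0 rose from 2114 ± 287 to 3471 ± 294 (log2 0.72, limma adjusted p = 0.0326) among 9 reference genes, the only one also adjusted over the list alone (median 0.11, camera adjusted p = 0.313). Too few genes were measured to test the lists of blood genes (1 gene, Alas2 at -0.42) and pituitary genes (2 genes, Pomc at -0.22 and Chga at 0.09). The 4 sex-linked genes were not tested as a list either, with Uty at -0.47 and Kdm5d at -0.83. No member of these lists passed.

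Genes near Egr1 or Egr3, counted as 1 set, changed more often than other genes. Within 10 Mb of Egr1, Pcdhb9, Syt4 and Camk4, a calcium-dependent protein kinase (log2 -1.06), fell and Pcdhb3 rose (log2 0.77). Within 10 Mb of Egr3, Tsc22d1 (log2 -1.22), Kctd4 (log2 -0.89), Fdft1 and Mtmr9 (log2 -0.62) fell and Lgi3 rose (log2 1.08). Of 4 tested Camk4 probe sets 2 passed, the brighter at log2 -0.89 (limma adjusted p = 0.00929). Other tested probe sets of Syt4, Tsc22d1, Kctd4, Fdft1, Mtmr9 and Lgi3 did not pass, and 1 or more had the opposite sign for Tsc22d1, Mtmr9 and Lgi3. All but Pcdhb9 and Syt4 were named here after their values were seen. Probe sequences were not given in the sources used here, so strain variants under the probes could not be checked. The values near Egr1 and Egr3 are therefore changes in signal, which need not be changes in expression. These 9 genes were among 191 tested in the windows (4.71%), against 162 of 10826 elsewhere (1.496%). The odds ratio was 3.25 (95% confidence interval 1.44 to 6.47, two-sided Fisher's exact test p = 0.00293, adjusted p = 0.00781 over 8 windows). Fisher's test counts each gene as independent, which neighbouring genes may not be, so its intervals may be too narrow and its p-values too small. Within 10 Mb of Egr3 alone 5 of 96 genes had changed (odds ratio 3.56, exact p = 0.0167), and of Egr1 alone 4 of 95, which did not pass (odds ratio 2.83, exact p = 0.0602). With 20 Mb windows 14 of 323 genes had changed (odds ratio 3.04, exact p = 5.02e-04). On the chromosomes of Egr1 and Egr3 22 of 658 had changed (odds ratio 2.37, exact p = 8.27e-04), and these ranked 1 and 2 of 20 chromosomes by the share of tested genes that changed. The test did not pass with 5 Mb windows (5 of 129 genes, odds ratio 2.60, exact p = 0.0504), with the stricter filter (odds ratio 1.92, exact p = 0.196), with no filter (8.05, exact p = 0.132) or without both doubted arrays (5.69, exact p = 0.175). The odds ratio moved to 6.41 without double knockout replicate 2, 8.62 without double knockout replicate 3 and 5.96 with no intensity trend.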

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

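The alternatives chosen after seeing the data were 2 doubted arrays left out together (wild type replicate 1, with dim controls, and double knockout replicate 2, of a female), sex chromosome genes left out, and genes within 20 Mb of Egr1 or Egr3 left out. The count of 229 probe sets was 586 at an adjusted p under 0.10, 10 with no filter, 131 with no intensity trend, 12 without both doubted arrays (fewer arrays) and 34 to 292 with single arrays left out. The other alternatives gave 182 to 290, among them 212 after quantile normalization (201 shared), 193 after a median shift, 241 without sex chromosome genes and 189 without genes near Egr1 or Egr3. Replicates with the same number did not deviate together (r = -0.147, 0.0013 and -0.101), and with a replicate block the count was 182, of which 140 were shared. Egr3 lost its call with no filter, no intensity trend and robust trend (-1.80 in each), without both doubted arrays (-1.88) and in 4 of the 6 fits with single arrays left out (-1.97 to -1.69), and kept it without wild type replicates 2 (-1.36) and 3 (-2.12). Egr1 ranged from 0.52 to 0.87 in the 6 fits. The number of lists called was 0 with an estimated correlation, 0 with the directional test of fry and 4 to 7 otherwise; robust trend gave no value for lists, since camera does not use it. The odds ratio near Egr1 and Egr3 lost its call at 2.60 with 5 Mb windows, 8.05 with no filter, 1.92 with the stricter filter and 5.69 without both doubted arrays.

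No list past the threshold changed sign under any alternative, nor did a named gene, whose sign could not turn with arrays left out because its groups did not overlap. Among the others, the sign turned with single arrays left out for Arc (-0.36 to 0.56), Kdm5d (-1.33 to 0.071), Egr4 (-0.029 to 0.52) and Kcnj13 (-1.08 to 0.048). So did the medians of the lists of reported Egr targets (-0.061 to 0.10), immediate early (-0.15 to 0.057), glutamate (-0.083 to 0.032), GABA (-0.091 to 0.043), ion channel (-0.034 to 0.027), interferon (-0.0085 to 0.070), oligodendrocyte (-0.047 to 0.25), astrocyte (-0.036 to 0.066), endothelial (-0.15 to 0.027), striatal (-0.25 to 0.13), hippocampal (-0.26 to 0.22), choroid plexus (-1.07 to 0.18) and meningeal genes (-0.18 to 0.050). Without both doubted arrays it turned for Arc (-0.31), Kdm5d (0.011) and the lists of reported Egr targets (-0.075), immediate early (0.0098), ion channel (0.020) and meningeal genes (0.012). With the mean of a gene's probe sets it turned for the glutamate (0.017), ion channel (0.071) and interferon lists (-0.037). It turned for the Egr targets (-0.030) and interferon list (-0.031) with no filter, for the interferon list (-0.046) with the stricter filter and for immediate early genes (0.0039) with a median shift. With no filter the prior degrees of freedom fell from 6.05 to 3.35; the filtered fit's p-values placed among the additional tests gave 93 calls, so more tests were part of the fall to 10. Of the named genes not past the threshold, some gained a call: Bdnf with robust trend and with a replicate block, Hsph1 after quantile normalization, P2ry12 with a replicate block and without double knockout replicate 1, Penk without wild type replicate 2, and Jund in 6 alternatives. Past the threshold, Lmo4 and Zbtb20 lost the call in all 6 fits with single arrays left out, Vip, Gabra2, Scn4b, Ntrk3, Nsdhl and Cap1 in 5, and Rplp0, Pou3f1, Idi1 and Hpcal1 in 4. The cause was not tested where none is given. Low signal over background limits the dimmer probe sets, which were tested only with no filter.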

Other observations

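The tests in this part chosen only after the result was seen are those on other splits of the arrays, on the array of the female and array brightness for the changed probe sets, on mislabelled arrays, on the position of the Egr1 probe set and on glial cells. The genes in the next sentences were also chosen after their values were seen. Of 16 tested regulators of G protein signalling 4 fell in the arrays labelled double knockout and none rose. These were Rgs20 (430 ± 105 to 207 ± 37.0, log2 -0.99), Rgs14 (431 ± 65.3 to 243 ± 20.3, log2 -0.78), Rgs8 (231 ± 25.2 to 133 ± 0.211, log2 -0.72) and Rgs10 (378 ± 12.2 to 257 ± 17.6, log2 -0.53). A second Rgs20 probe set differed by -0.33 and did not pass. Both collagen VI genes tested rose, Col6a1 by 1.39 and Col6a2 by 0.98 on the log2 scale. Of 9 copine genes 2 fell, Cpne9 and Cpne5 (402 ± 4.71 to 187 ± 11.1, log2 -1.04). C1ql3, a secreted synaptic protein, fell from 1146 ± 216 to 560 ± 93.6 (log2 -1.01, limma adjusted p = 0.0187).

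Scd1, a fatty acid desaturase, fell from 883 ± 135 to 430 ± 61.6 (log2 -1.01, limma adjusted p = 0.0122). Acly, which makes acetyl-CoA, fell from 863 ± 46.5 to 584 ± 36.9 (log2 -0.55, adjusted p = 0.0363), and Abca1, a cholesterol exporter, rose from 340 ± 31.8 to 589 ± 55.1 (log2 0.76, adjusted p = 0.0182). The transferrin receptor genes Tfrc and Tfr2 rose, by 0.59 and 0.76 on the log2 scale, on 1 probe set each, and the other Tfrc probe sets differed by 0.81 and 0.86 and did not pass. A second Tfr2 probe set differed by 0.25 and did not pass. Ly86 and Nrros, known from macrophages and microglia, fell (log2 -0.81 and -0.93). Of 103 changed genes with at least 2 tested probe sets, 75 had another probe set that moved the same way at an unadjusted limma p under 0.05, 28 had none and 21 had a probe set of opposite sign.

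The first pattern was the 229 probe sets past the threshold, for which the 10 splits of the 6 arrays are too few for a share under 0.05; the labelled split was the only 1 to give 229, and the highest other split gave 2. Flanking DNA carried with the targeted alleles as the whole cause is argued against, since 8.19% of the changed genes lay within 20 Mb of Egr1 or Egr3 (exact 95% interval 4.55% to 13.4%), but the odds ratio of 3.25 within 10 Mb is consistent with it as part of the cause. The arrays had been scaled to equal brightness and their log2 medians differed by 0.0885, so quantile normalization had little to remove. It cannot show a difference in total RNA. A brightness difference left by that scaling is argued against, as 87.8% of the changed probe sets kept sign and call after quantile normalization. The array of the female as the whole cause is argued against only for the probe sets that the fits below could call. On the probe sets called without each, male double knockout replicates 1 and 3 showed medians of 73.0% and 94.5% of the change. The lower quartiles were 55.1% and 75.3%. Each of these fits held the array of the female and the other male. Probe sets changed in the female alone were therefore unlikely to be called, and the test says little about them. An earlier test by count did not reach its bound of 80. Without the array of the female 53 passed, and up to 8 in the other splits of the remaining 5. The array of the female as part of the cause, loss of the targeted factors, strain differences elsewhere in the genome and RNA quality, by the Gapdh ratio, stay open and were not tested.

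The second pattern was the Egr1 signal, higher in all 3 arrays labelled double knockout though not past the threshold. Mislabelled arrays, as an exchange of the whole groups, cannot be told apart from correct labels, because Egr3 changed by -1.80 while Egr1 differed the other way. A brightness difference left by the deposited scaling is argued against, with the limit given above, because 92.4% of the Egr1 difference stayed after quantile normalization. So is double knockout replicate 1 as a wild type array. Relabelling it could not account for the Egr1 pattern, since double knockout replicates 2 and 3 had the highest Egr1 signals (2647 and 2657). The brighter Egr3 probe set read 339 in double knockout replicate 1, the lowest of the arrays. On the probe sets called without it, that array showed a median of 73.0% of the change of double knockout replicates 2 and 3 (quartiles 55.1% and 87.5%), where wild type arrays left out in turn showed 15.5% to 33.5%. A probe set outside the disrupted part of the gene may read a transcript that makes no working protein, which cannot be told apart from intact Egr1 by the log2 difference of 0.67, since neither the probe positions nor the alleles were given, and a biological rise of its transcription was not tested.

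The third pattern was the lower cholesterol synthesis genes, with a median of -0.45. Fewer oligodendrocytes or astrocytes are argued against, because the lower quartiles of their lists, -0.08 and -0.12, lay above that median. A brightness difference left by the deposited scaling, with the limit given above, and the array of the female are argued against. Of the median, 97.9% stayed after quantile normalization and 116% without the array of the female. Fewer microglia, whose list had a median of -0.46, were not tested as a cause. An effect of the labelled genotype stays open as a hypothesis, and so do feeding and time of day, which were not tested.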
